A study of Mus musculus with 23 samples.

How the data were processed

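Tumour DNA and reference DNA were hybridised together to Agilent mouse arrays of 105029 spots. The tumour DNA came from spleen B cell lymphomas of mice, labelled with Cy3. The reference, a pool of 5 normal spleens that lack Cd3e, was labelled with Cy5, per the labels. There was no dye swap. The cells were grown in suspension, and DNA was extracted with phenol and chloroform and labelled with a random-primer kit for this type of array. Samples were grouped by days in culture as the labels give it, into day 0 (n = 10) and early passage (n = 13), and are named by tumour number. The series text calls all 23 samples lines that lack Atm, while the labels give an intact Atm to 7 of the early-passage lines and put 10 samples at day 0. The groups follow the labels.

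The scanner files hold each spot's intensity in both channels, per the file headers. The authors used Agilent Feature Extraction 10.5.1.1 (7 arrays) or 10.7.1.1 (16 arrays), which gave 2 image extraction protocols, called earlier and later here. The processed intensity of each channel is background-subtracted and dye-normalised by a linear factor within the array, per the file headers. It is not normalised between arrays. The files also hold other columns with a 0 or 1 per spot, which mark spots well above background or not uniform, per the file headers. The deposited value table is in log2 units, tumour over reference. It equalled the log2 ratio of the processed intensities in each scanner file (largest difference 5.0e-10), was not centred (column medians −0.0621 to 0.0521), and so gave the same results by construction. Probe positions are in build mm9 (NCBI 37), per the file headers. The gene table used for names is on a later build and served for names only.

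The log2 ratio was computed from the processed intensities, after control spots (4712), spots with no place in the genome (823) and spots marked as not uniform or as outliers in their population (83 to 154 per array) were left out. Spots of the same probe were averaged (756 probes), which gave 97982 probes, 92568 of them autosomal, 5006 on X and 408 on Y. Each array was centred on its autosomal median. The tumour signal was 2.25 to 6.67 times its background and the reference signal 3.63 to 12.9 times. A mean of 99.0% of spots lay well above background (95.5 to 99.7%), and 87704 probes did so on all arrays. The number of arrays limits the precision.

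Segments were found on each chromosome by optimal partitioning, with a penalty of 3 times the natural logarithm of the probe number, after values were clipped at 3.5 noise units from the median of 11 neighbouring probes. A segment of at least 5 probes was called gained at a mean of 0.2 or more and lost at −0.2 or less. Recurrent regions are runs of probes called in more arrays than the 95th percentile of the genome-wide highest count over 1000 random circular shifts. Autosome means and locus means were tested against 0 by exact two-sided sign-flip permutation tests, adjusted by Benjamini and Hochberg over 19 autosomes or 6 loci. An autosome also had to reach a mean of 0.1 in size. Genes were tested with limma (treat, beyond 0.1) on the mean of all probes within 250 kb (at least 5 probes), and genes spanning over 3 Mb were left out. Bins of 1 Mb with at least 5 probes (2397) were compared between stages with limma. The percent altered was compared by a two-sided permutation test with 100000 resamples, exact where a group held under 10 values. The reference is 1 pool, so tests against it leave out the spread of normal samples. The threshold was 0.05 throughout.

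The groups, tests, thresholds, gene lists and most alternatives were fixed before the data were examined. Named genes were Atm and Cd3e, then list genes past the test over all genes (at most 8 per list) or in called segments of at least 4 lines or 3 day 0 samples, at most 30 per stage with the largest means first. To these came up to 3 genes nearest each peak of a recurrent region, list genes with a segment mean of −1.5 or lower or 1 or higher in any array, and the 5 bins per direction with the smallest p. That the limit of 30 covers these list genes together was settled after the values were seen. The 6 lists cover NF-kB activators, NF-kB inhibitors, B cell lymphoma oncogenes, tumour suppressors, genes of DNA damage response and repair, and housekeeping genes as a control. A list gene was matched by name, or by 1 synonym (5 genes in all lists), and 15 genes were not on the array by name. Tcf3 was left out after its value was seen, since the array uses that name for a gene on another chromosome. The values of some list genes are not reported here, and these genes are counted in the totals of their lists. No list of cell type markers was used, because DNA carries no expression.

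Scan dates fell into 3 batches, with gaps over 90 days between them. The first held 7 lines, the second 6 day 0 samples, and the third 4 day 0 samples and 6 lines. Stage and batch are therefore partly confounded, and only the third batch compares them directly. The 9 matched tumours are those whose number is the same at both stages, and 123203 at day 0 was not paired with 12303 at early passage. Pairing was checked by correlating each pair's deviations from the stage means over bins. The r was 0.110 to 0.752, above 0.1 in 9 of 9 pairs. With the number as a replicate block limma called 5 bins higher and 12 lower.

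The alternatives were normexp background correction (offset 50, on median signals minus background medians), centring on the mode, the deposited table, only probes well above background on all arrays, and correction of each array for the GC content of the probe sequences by lowess (span 0.3, 2 iterations). The normexp values were centred but not dye-normalised, and the offset pulls the ratios of dim probes together. Others changed the call limit (0.15 or 0.3), the probes per segment (10), the penalty (doubled), the length of altered stretches (3 Mb or longer), the gene window (100 kb, at least 3 probes), the bins (5 Mb) or the size limit (none). Arrays were left out in turn, lines were restricted to 1 protocol or to those labelled as lacking Atm, and models had the tumour number, the slide or the protocol as a term. Chosen after seeing the data were the settings by scan batch, those without the 2 noisiest arrays, and those that join GC correction with the tumour number or the scan batch.

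The steps were tested on simulated data. Of planted stretches of 40 probes, 73.9% were recovered at a log2 ratio of 0.6, 78.7% at −0.6 and 14.8% at 0.3, and of stretches of 200 probes at 0.3, added after that, 79.1%. False calls covered 0.324% of probes. Planted genes were recovered to 100% in 13 arrays and 99.6% in 10, with 0 false calls. Planted bins were recovered to 86.2%, with 16 false calls in 2397. The simulated noise was each array's residual from its segment means, shifted along the genome by a random amount per array. It therefore lacks shifts that arrays share at one place, such as those that follow GC content, and the spread between tumours. Planted gene changes were equal on all arrays of a group. The rates thus say nothing of false calls from shared shifts. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.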

Results

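DNA copy number was measured by array comparative genomic hybridisation, in which tumour DNA and reference DNA compete for the same probes, in splenic B cell lymphomas of mice. The mice lacked T cells through loss of Cd3e, a chain of the T cell receptor complex, and the series text gives loss of Atm, the kinase that signals DNA double-strand breaks, for all tumours. The study concerns lymphomas that arise in this setting and depend on NF-kB, a family of transcription factors that promotes B cell survival. Of the 23 arrays, 10 held DNA of tumour cells at day 0 of culture and 13 held DNA of cell lines at an early passage. For 9 tumours both stages were measured. The reference on every array was 1 pool of spleen DNA from 5 normal mice. Values are log2 ratios of tumour over reference, centred on the autosomal median of each array, and ± gives the SD over arrays unless SE is written. Positions are in mouse build mm9 (NCBI 37). The tumour signal was 2.25 to 6.67 times its background, with a mean of 4.95 ± 1.2 (n = 13) in the lines and 3.65 ± 1.09 (n = 10) at day 0. The noise between neighbouring probes was 0.402 ± 0.154 on the log2 scale (n = 23), and it was highest in 122378 at day 0 (0.803) and in the line 12303 (0.720). The number of arrays limits the precision of every mean.

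The probes of Atm lay on both sides of the reference. Over its 6 probes (chromosome 9, 53253537 to 53344491) the mean was −0.33 ± 0.18 in the lines (n = 13) and −0.09 ± 0.25 at day 0 (n = 10). In the lines the probes starting at 53253537, 53273288 and 53321244 had means of −0.78 ± 0.33, −0.82 ± 0.37 and −0.83 ± 0.38, and at day 0 −0.34 ± 0.47, −0.026 ± 0.25 and −0.80 ± 0.67. The probe at 53290451 lay above the reference in every array, with means of 0.80 ± 0.19 in the lines and 0.83 ± 0.11 at day 0. The labels give 7 of the 13 lines an intact Atm gene, against the series text, and the other 6 a lost one. They also conflict within tumours, since every day 0 sample is labelled as lacking Atm. The lines 122378, 141645, 161336, 196303, 67506 and 178119 are labelled intact and their own day 0 samples as lacking it. The lines labelled as lacking Atm (n = 6) had the lower mean at 2 of 6 probes, at 53290451 (0.66 ± 0.10 against 0.92 ± 0.17, n = 7) and at 53273288 (−1.01 ± 0.28 against −0.65 ± 0.36). They had the higher mean at the other 4, at 53303891 (0.016 ± 0.14 against −0.34 ± 0.29), 53321244 (−0.64 ± 0.41 against −0.99 ± 0.28), 53253537 (−0.66 ± 0.31 against −0.88 ± 0.34) and 53344432 (−0.16 ± 0.13 against −0.17 ± 0.44). The ranges of the 2 labels overlapped at all 6 probes, and the difference was not tested. Label and batch are confounded: all 6 lines labelled as lacking Atm were in scan batch 1 with the earlier image extraction protocol, and 6 of the 7 others in scan batch 3 with the later one. Cd3e, lost in tumours and reference alike per the labels, had means of 0.60 ± 0.21 in the lines and 0.19 ± 0.22 at day 0 over its own probes. With the gene lost on both sides, its ratios could not show the loss. Why they lay above 0 was not tested.

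Which regions the lines had gained or lost relative to normal spleen was asked first. Malt1, a paracaspase that activates NF-kB downstream of the antigen receptor, had the largest mean of all listed genes. Its window on chromosome 18 (gene at 65611200 to 65636075) lay at 2.32 ± 1.03 (n = 13; a 4.99-fold ratio; limma, adjusted p = 2.9e-05), above 0 in 13 of 13 lines. Pmaip1, which encodes the pro-apoptotic protein Noxa, lies on the same chromosome at 66619195 and was gained to 1.71 ± 0.77 (n = 13; limma, adjusted p = 3.1e-05). A stretch of 0.513 Mb at 65507824 to 66020370, with Malt1, Zfp532 and Sec11c, lay in a segment with a mean of 1 or more in 12 of 13 lines. That stretch was singled out after its values were seen. The far end of the same chromosome went the other way. Its last 9.35 Mb (81414422 to 90762649) were lost in up to 13 of 13 lines, and the peak at 85150701 to 90762649, with Cbln2, Socs6 and Rttn, lay at −1.07 ± 0.43 (n = 13).

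**Figure D1:**
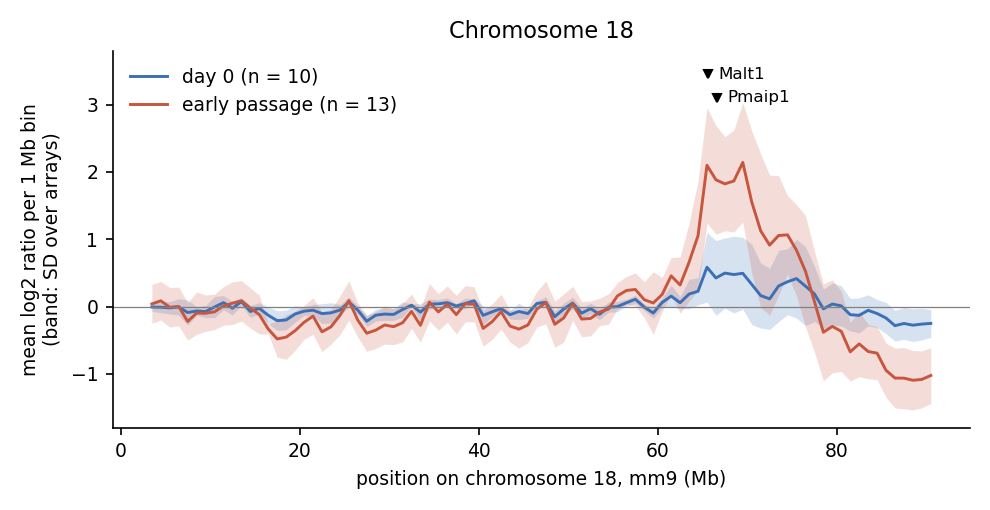
Mean log2 ratio per 1 Mb bin (vertical axis) along chromosome 18 in mm9 (horizontal axis, Mb) at day 0 (n = 10) and in the early-passage lines (n = 13); lines are means, bands the SD over arrays, and triangles mark Malt1 and Pmaip1. The early-passage mean is 2.14 in the bin starting at 69000001 and −1.08 in the bin starting at 89000001.

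Among the lists fixed before the data were examined, 17 of 30 NF-kB activators were gained in the lines and 0 lost (limma, beyond a log2 ratio of 0.1; 18 gained when adjusted over the list alone). Besides Malt1 these included Tnfrsf1a, a TNF receptor, at 0.64 ± 0.23 (adjusted p = 2.1e-05), and Relb, an NF-kB subunit, at 0.43 ± 0.26 (n = 13 each). After correction for the GC content of the probes 4 activators were gained. Malt1 then lay at 2.32 and Tnfrsf1a at 0.64, while Relb lay at −0.04. For comparison, 9 of 16 housekeeping genes and 7458 of all 22202 genes were gained (4 and 3649 after GC correction). A difference from these shares was not tested, so no preferential gain of NF-kB activators is shown. Nfkb1, which encodes the p50 subunit, was not called (0.22 ± 0.31, adjusted p = 0.133), nor was Bcl10 (0.32 ± 0.43, adjusted p = 0.0706). Of the NF-kB inhibitors 5 of 16 were gained and 0 lost (4 gained when adjusted over the list alone, 3 after GC correction). They included Traf3, which restrains the alternative NF-kB pathway, at 0.51 ± 0.56 (n = 13, adjusted p = 0.0166), and Ptpn6, the phosphatase SHP-1, at 0.61 ± 0.24, which lay at 0.27 after GC correction (adjusted p = 0.0861).

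Of the B cell lymphoma oncogenes 19 of 41 were gained and 0 lost (20 gained when adjusted over the list alone, 16 after GC correction). Foxp1, a forkhead transcription factor, and Ccnd2, which encodes cyclin D2, both lie on chromosome 6 and were gained to 0.56 ± 0.23 and 0.53 ± 0.24 (n = 13 each; limma, adjusted p = 4.7e-05 and 9.1e-05; Foxp1 0.37 with normexp). The kinase gene Akt1 on chromosome 12 was gained to 0.79 ± 0.74 (adjusted p = 0.0049) and lay at 0.46 after GC correction (adjusted p = 0.0643). Myc was not called, with a mean of 0.07. Of the tumour suppressors 19 of 42 were gained and 3 lost (19 and 3 when adjusted over the list alone; 11 and 1 after GC correction). The lost ones were the receptor phosphatase gene Ptprk at −0.44 ± 0.24 (adjusted p = 0.0004), the ubiquitin ligase gene Hace1 at −0.45 ± 0.37 (adjusted p = 0.0038; −0.28 and adjusted p = 0.0903 after GC correction; −0.15 and adjusted p = 0.248 with normexp) and the ephrin receptor gene Epha7 at −0.31. Tnfaip3, an inhibitor of NF-kB signalling, was not called, with a mean of −0.08. Stk11, which encodes the kinase LKB1, was gained to 0.62 ± 0.32, and lay at 0.11 after GC correction (adjusted p = 0.759).

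Of the genes of DNA damage response and repair 15 of 36 were gained and 1 lost (15 and 1 when adjusted over the list alone; 13 and 0 after GC correction). Fancd2, of the Fanconi anaemia pathway, lay at 0.65 ± 0.22, Palb2, the partner of Brca2, at 0.40 ± 0.20, and the lost one, the DNA ligase gene Lig4, at −0.17 (n = 13 each). Of the housekeeping genes taken as a control list 9 of 16 were gained and 0 lost (11 gained when adjusted over the list alone, 4 after GC correction), with Gapdh on chromosome 6 at 0.64 ± 0.23. Over all 22202 genes tested, limma called 7458 gained and 2590 lost, and neighbouring genes share probes. After GC correction 3649 were gained and 1728 lost, of which 3086 and 1538 were the same genes as without it. With another background correction, by normexp, 4443 were gained and 794 lost. In the 6 lines of the later image extraction protocol alone 686 were gained and 483 lost. There 13 of the 30 named genes of the lines kept their call. All 30 kept it in the lines of the earlier protocol, and in those labelled as lacking Atm.

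By whole autosome, chromosome 6 was gained in the lines (0.18 ± 0.18, above 0 in 11 of 13) and so was chromosome 11 (0.10 ± 0.08, 12 of 13). Chromosome 10 was lost (−0.10 ± 0.10, below 0 in 13 of 13) and so was chromosome 14 (−0.10 ± 0.15, 11 of 13). Adjusted p-values were 0.0087, 0.0019, 0.0015 and 0.0087 in that order (exact two-sided sign-flip permutation test, adjusted over 19 autosomes, n = 13). Chromosomes 10, 11 and 14 lie at the size limit of 0.1. Without 16508 or 39317 chromosome 6 alone was gained, without 12303 chromosomes 6 and 18, and without 122378, 196303, 12437 or 47990 chromosome 18 was gained besides 6 and 11. Without 141645, 16508 or 25487 chromosome 14 alone was lost, and without 161336 or 67506 chromosome 10 alone. Chromosome 11 lay at 0.03 after GC correction and was not called, chromosome 18 was gained instead (0.11), and with normexp 0 autosomes were lost (0 also at an unadjusted p under 0.05 beyond the size limit).

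Recurrent regions, altered in more lines than random shifts of the calls along the genome allowed, numbered 16 gained (87.9 Mb) and 32 lost (252 Mb). The gained regions included chromosome 6 at 112118681 to 128920622, which reached 12 of 13 lines (0.48 ± 0.19 at its peak), chromosome 10 at 79117736 to 81045199 with Stk11, which reached 13 (0.62 ± 0.34), and chromosome 12 at 113346835 to 114627571 with Akt1, which reached 11. The longest loss was chromosome 14 at 80893020 to 118134259 (37.2 Mb), with the protocadherin genes Pcdh9 and Pcdh17 and with Tdrd3 nearest its peak, at −0.40 ± 0.31 (n = 13). Chromosome 10 at 27311851 to 38751762, with Ptprk, was lost in up to 10 lines. After GC correction there were 7 gained and 9 lost regions, and 4 of the 16 gained and 9 of the 32 lost regions overlapped one of them, among them the gain and the loss on chromosome 18, the gain on chromosome 6 and the long loss on chromosome 14. The gains with Stk11 and Akt1 and the loss with Ptprk overlapped none. The lines of the later image extraction protocol alone (n = 6) gave 8 gained and 2 lost regions.

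The same question was asked of the tumour cells at day 0. The gene of the NF-kB subunit p50, Nfkb1, lay at 0.47 ± 0.39 and that of Bcl10, an adaptor that binds Malt1, at 0.55 ± 0.44 (n = 10 each), in called gains of 6 and 7 of 10 samples. Both lie in a recurrent gain on chromosome 3 at 134094434 to 156094671, which reached 7 of 10 samples and had a peak at 143172609 to 149435884 with a mean of 0.53 ± 0.42. Malt1 lay at 0.66 ± 0.70, in called gains of 6 of 10 samples, within a recurrent gain on chromosome 18 at 65001075 to 69927677 (0.50 ± 0.53). The other recurrent gains were chromosome 4 at 154350728 to 154374230, chromosome 6 at 122659660 to 129587665, and chromosome 12 at 113041191 to 114664569 with Akt1 (0.58 ± 0.60), which reached 8 of 10. Those on chromosomes 4 and 12 overlapped no region found after GC correction. The 2 recurrent losses overlapped immunoglobulin loci. The one on chromosome 6 at 68388902 to 70668721 lay within Igk, and the one on chromosome 12 at 114692582 to 121241648 began within Igh and ran on past the end of that locus at 117265934.

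No gene passed the test over all 22202 genes at day 0 (limma beyond 0.1: 0 gained and 0 lost, lowest adjusted p = 0.30, 2075 at an unadjusted p under 0.05; limma without the size limit: 3419 gained and 1369 lost). The counts in the lists were therefore 0 as well. When adjusted over the list alone, 3 of 30 NF-kB activators were gained, Nfkb1 (adjusted p = 0.0361), Bcl10 and Tnfrsf1a (0.0347 each), and Malt1 was not (0.0677). In the same way 1 of 16 NF-kB inhibitors was gained (Ptpn6), 2 of 41 oncogenes (Foxp1 among them, 0.0292), 0 of 42 tumour suppressors, 0 of 36 repair genes and 1 of 16 housekeeping genes (Gapdh, 0.0294). No autosome was called (exact sign-flip test, 0 gained and 0 lost; 1 gained and 0 lost at an unadjusted p under 0.05). Chromosomes 10 (−0.043 ± 0.059, below 0 in 9 of 10) and 11 (0.054 ± 0.070, above 0 in 10 of 10) passed the adjusted test (0.0371 each) but not the size limit. Chromosome 6 was past the size limit but not the test (0.16 ± 0.17, above 0 in 8 of 10, exact p = 0.0195, adjusted 0.102), and was called gained without 122378. In the 6 day 0 samples of 1 scan batch alone limma called 1268 genes gained and 444 lost. Among the named genes of day 0, 9 passed the test in that batch and 0 in the 4 day 0 samples of the other.

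How much of the genome was altered at each stage was compared next. In the lines 34.1 ± 14.5% of the autosomal probes lay in called segments (n = 13), 18.3 ± 7.36% gained and 15.8 ± 8.03% lost. At day 0 it was 13.4 ± 19.1% (n = 10), and 122378 stood apart at 66.8%, against 1.69 to 15.0% in the others, whose mean was 7.50%. The value of 122378 depended on the processing, at 28.1% after GC correction and 0.28% with normexp. The difference was 20.6 points (two-sided permutation test, p = 0.00796). In the 9 matched tumours, with the replicate block, it was 14.5 points (exact p = 0.121), and 14.5 unpaired (exact permutation p = 0.0687). Of these pairs only 122378 was lower in the line, at 19.2% against 66.8% at day 0. Within the only scan batch that held both stages the means were 38.4 ± 15.9% (n = 6) and 20.8 ± 30.9% (n = 4), a difference of 17.6 points (exact permutation p = 0.271). The day 0 mean of that batch included 122378, beside 1.69, 3.63 and 11.1% in its other samples. After GC correction the means were 19.2 ± 11.4% and 8.79 ± 7.50%, a difference of 10.4 points (p = 0.0163). With normexp they were 22.6 ± 17.6% and 4.60 ± 4.49% (p = 0.00358), and with a call limit of 0.3 the difference was 9.74 points (p = 0.0710).

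**Figure D2:**
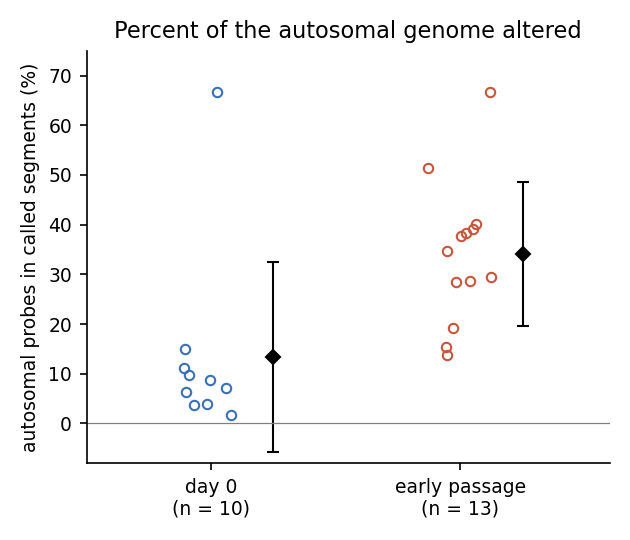
Percent of autosomal probes in called segments (vertical axis) for each day 0 sample (n = 10) and each early-passage line (n = 13); circles are arrays and diamonds with bars the mean ± SD. The lines lie between 13.8 and 66.7%, and at day 0 122378 lies at 66.8% and the other samples between 1.69 and 15.0%.

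Which regions differed between lines and day 0 was tested over 2397 bins of 1 Mb. The 5 higher bins with the smallest p were all on chromosome 18 between 65000001 and 70000000, and hold Malt1 (1.51 ± 0.29 SE higher, adjusted p = 0.0052), Pmaip1 (1.46 ± 0.28), Cidea (1.33 ± 0.25), Mc5r (1.39 ± 0.27) and Tcf4 (1.65 ± 0.30, adjusted p = 0.0042), the last a transcription factor of B cell and dendritic cell development. Of the 5 lower bins with the smallest p, 3 lay at the far end of chromosome 18, near Dok6 and Fbxo15 (−0.82 ± 0.14, −0.77 ± 0.14 and −0.78 ± 0.14 SE). The other two were chromosome 11 at 73000001 near the olfactory receptor gene Olfr385 (−0.21 ± 0.04) and chromosome 7 at 72000001 near Tjp1, a gene of tight junctions (−0.15 ± 0.03). The Tjp1 bin was not called after GC correction (−0.10, adjusted p = 0.194) or with normexp (−0.046, adjusted p = 0.0968), and the 3 bins at the far end of chromosome 18 were called with normexp at −0.40 to −0.42. In all, limma called 96 bins higher, with a mean difference of 0.27, and 443 lower, with a mean of −0.20. With normexp 378 were higher and 321 lower, so which direction held more bins changed with the background correction.

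The 443 lower bins lay on 19 chromosomes, with 59 on chromosome 3. With the replicate block over the 9 matched tumours limma called 5 bins higher and 12 lower, among which the Malt1 bin (1.49 higher, adjusted p = 0.0534) and the Tjp1 bin (−0.13, adjusted p = 0.0752) were not, though the difference at Malt1 was about as large as without the block. With the scan batch as a covariate it called 0 higher and 0 lower (61 and 172 at an unadjusted p under 0.05), and the chromosome 18 differences were then 1.67 to 1.93 in the 5 higher bins (adjusted p = 0.156). Within the scan batch that held both stages 4 were higher and 0 lower (58 and 13 at an unadjusted p under 0.05). Single arrays moved the higher count over 1.5 times. Without 1 day 0 sample it was 47 (161336), 33 (196303), 405 (122378), 38 (67506), 28 (123203), 31 (178119), 47 (180764), 36 (12437) or 51 (47990). Without 1 line it was 190 (122378), 58 (141645), 58 (12303), 63 (12437) or 52 (16508). The lower count was 289 without 196303, 752 without 122378, 292 without 123203, 257 without 178119 and 277 without 12437, all at day 0.

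Malt1 was higher in the line than at day 0 in 9 of 9 matched tumours. The mean difference was 1.56 ± 0.98 (n = 9, exact two-sided sign-flip p = 0.00391, the smallest that 9 pairs allow), from 0.32 in 47990 to 3.21 in 141645. In 180764 Malt1 was already at 2.57 at day 0 and reached 3.09 in the line. In 47990 it went from 0.18 to 0.50, the lowest value of any line. In the 4 tumours with both stages in 1 scan batch the mean difference was 2.35 ± 0.67. This comparison of pairs was chosen after the values were seen.

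**Figure D3:**
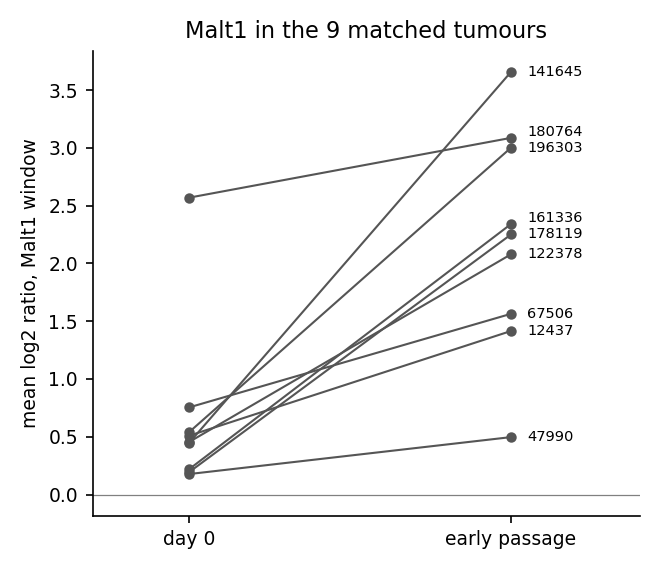
Mean log2 ratio over the Malt1 window (vertical axis) at day 0 and early passage; each line joins the 2 stages of 1 of the 9 matched tumours and carries its number. All 9 go up, from 0.18 to 2.57 at day 0 to 0.50 to 3.66 in the lines.

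Whether each line carried the profile of its own tumour was asked of the 9 matched numbers. Over the 1 Mb bins the mean Pearson r between a day 0 sample and its own line was 0.674 ± 0.146 (0.478 to 0.901), against 0.454 over all pairings (exact one-sided permutation p = 2.76e-06, the smallest that 362880 pairings allow). These correlations are across bins within a pair, and bins are not independent replicates. Of the day 0 samples 8 of 9 correlated best with their own line, the exception being 122378, and after GC correction 9 of 9 did. Of the lines 5 of 9 correlated best with their own day 0 sample. Mean r was 0.564 in the 4 pairs from 1 scan batch (exact p = 0.0417, the smallest possible) and 0.763 in the 5 pairs across batches (exact p = 0.00833, the smallest possible).

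Antigen receptor loci, which lose DNA when a lymphocyte rearranges them, were tested for a clonal B cell pattern. The reference was spleen DNA, which includes B cells that have rearranged their own immunoglobulin loci. Gained and lost are therefore relative to that pool and are no absolute copy numbers. In the lines Igh, the heavy chain locus (chromosome 12, 114458469 to 117265934, 132 probes), was lost at −1.86 ± 1.55 (below 0 in 12 of 13, adjusted p = 0.0073). Igk, the kappa light chain locus (chromosome 6, 67496059 to 70689790, 117 probes), was lost at −0.76 ± 1.03 (9 of 13, adjusted p = 0.0293). Igl, the lambda locus, was gained (0.12 ± 0.11, above 0 in 12 of 13, adjusted p = 0.0117; 0.33 after GC correction, adjusted p = 0.0051), and the T cell receptor loci Tcra/Tcrd (−0.08 ± 0.21), Tcrb (−0.03 ± 0.33) and Tcrg (0.16 ± 0.77) were not called (exact two-sided sign-flip tests over 6 loci, n = 13). Without 122378, 12303, 178119, 12437, 16508 or 39317 Igh alone was lost, and so it was after GC correction. Without 25487 Tcra/Tcrd was lost besides Igh and Igk. Neither locus was called with normexp (0 loci lost, 0 also at an unadjusted p under 0.05). That setting adds 50 to both channels, while the dimmest array had a median tumour signal of 124 over a background of 55. It pulls the ratios of dim probes together and so says little of deletions at these loci. At day 0 Igh lay at −1.22 ± 1.13 (below 0 in 8 of 10, exact p adjusted to 0.0703) and Igk at −0.40 ± 0.72 (adjusted 0.227), so 0 loci were called lost by the sign-flip test (1 at an unadjusted p under 0.05). Igh was called lost at day 0 without 123203 and after GC correction (adjusted p = 0.0410). Igl lay at 0.12 ± 0.14 and was not called (exact p adjusted to 0.0879), but was gained after GC correction (0.20, adjusted p = 0.0410). Between all lines and all day 0 samples the difference at Igh was −0.64 (adjusted p = 0.703, two-sided permutation test). Within the 9 matched tumours Igh was lower in the line in 9 of 9, by a mean of −0.68 ± 0.60 (exact two-sided sign-flip p = 0.00391, the smallest that 9 pairs allow; adjusted 0.0234 over 6 loci), and in 4 of 4 within the scan batch that held both stages. This paired test was chosen after the values were seen, and the other loci did not pass it. Only 16 of 132 probes at Igh and 39 of 117 at Igk lay well above background on all arrays, so the sizes of the log2 values at both loci are uncertain.

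**Figure D4:**
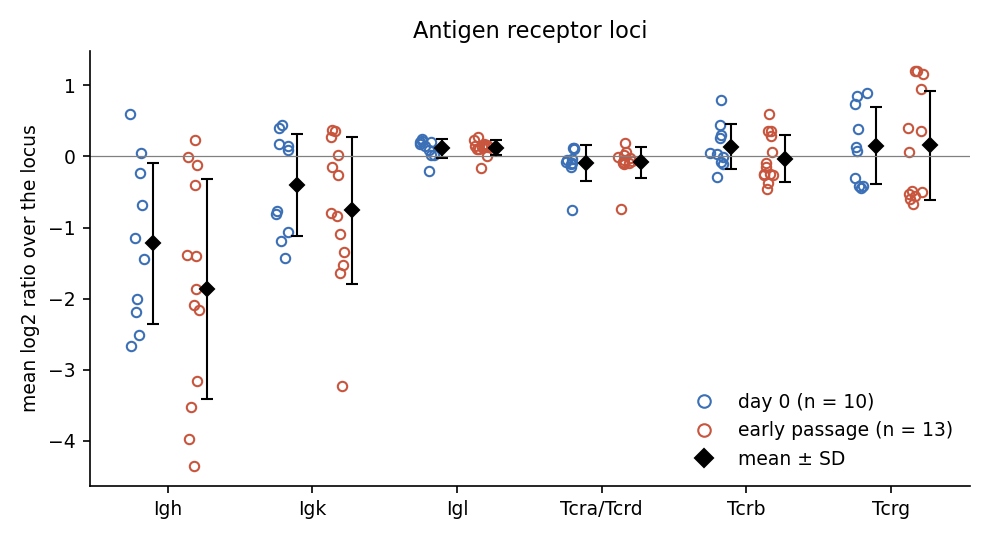
Mean log2 ratio over each antigen receptor locus (vertical axis) for the 6 loci (horizontal axis) at day 0 (n = 10) and in the early-passage lines (n = 13); circles are arrays and diamonds with bars the mean ± SD. Values at Igh reach −4.35 in the lines, and the means at Igl and the T cell receptor loci lie between −0.09 and 0.16.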

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

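The tests of scan batch, of dilution and of mislabelled lines, the ratio of bins left after the planned GC correction, and the tests of autosome and locus means between stages were chosen only after the result was seen. Values at day 0 that stood apart from the other 9 samples are given first. The gap to the nearest sample exceeded Dixon's limit at 26 ends among 57 measures, and 16 of the 26 came from 122378. Chance gives about 1 in 20 for unselected measures. Many of these overlap, however, and many genes were named for their values in the same samples, so the count is no measure of an excess over chance. The sample 122378 was highest in noise (0.803), in percent of the autosomal genome altered (66.8%; 28.1% after GC correction and 0.28% with normexp), and in the means of chromosomes 5 (0.14), 7 (0.29), 11 (0.24) and 15 (0.38). It was also highest at Rela (1.54), Tnfrsf13c (1.02), Mef2b (0.67), Ep300 (1.01), Kmt2d (1.38), Stk11 (1.49), Xrcc6 (1.09), Pms2 (1.4), Actb (1.32) and Cd3e (0.41). The sample 141645 was lowest on chromosomes 2 (−0.086) and 10 (−0.20) and at Igl (−0.20). The sample 67506 was lowest on chromosome 14 (−0.45) and at Tcra/Tcrd (−0.75). The sample 12437 was highest on chromosome 16 (0.13) and at Traf3 (1.68). The sample 180764 was highest at Malt1 (2.57) and Pmaip1 (1.66). The sample 123203 was highest at Tet2 (1.49).

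Of 25 differences between stages in autosome and locus means, 2 passed an unpaired permutation test, which took no account of the scan batch. Chromosome 3 was lower in the lines by −0.14 (adjusted p = 0.00575), with means of −0.09 ± 0.05 (n = 13) and 0.05 ± 0.09 (n = 10), and chromosome 13 by −0.038 (adjusted p = 0.0402). The chromosome 13 difference is smaller than the size limit of 0.1 used for autosome calls. The percent of the autosomal genome altered was 20.6 points higher in the lines (p = 0.00796). Chromosome X, which the comparisons did not use, had its highest mean in 47990 at day 0 (0.73). The Y mean of that sample was −2.64, and 67506 at day 0 had 0.72 on X and −2.46 on Y. The high X value thus came with a low Y value and was not particular to 47990. It cannot be read as a gain of X in the tumour, since the sex of the animals was not taken into account.

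Many bins across 19 chromosomes were slightly lower in the lines than at day 0 (443 bins, mean −0.20), beside 96 that were higher. Of 100 splits into 13 and 10 arrays 1 gave as many lower bins and 1 as many higher ones, the real split in both cases (highest others 0 and 25). Such splits break up the tumour pairs and the scan batches. Among splits that part as many pairs 1 and 2 of 100 did (highest others 375 and 197, median of the others 0 in both directions). These splits swap the stages of random pairs, so some keep or mirror much of the real split. Their high counts therefore cannot tell the stage from another structure in the samples. So many bins are therefore unlikely by a random split, but 100 splits cannot exclude it. Against the GC content of the bins as the whole cause, 373 bins were lower after correction for it (a ratio of 0.842 to the 443), of which 345 were the same bins. The scan batch stays open. Bins chosen from the other 2 batches differed by −0.127 within the batch that holds both stages, against −0.20 where they were chosen. The lines there lay at −0.27 ± 0.13 (n = 6) and day 0 at −0.14 ± 0.16 (n = 4). The exact unpaired permutation p was 0.210, the smallest possible being 0.00476. That test left out the pairing of the 4 day 0 samples with their own lines, and these samples include 122378, the noisiest array. With the batch as a covariate limma called 0 bins (61 higher and 172 lower at an unadjusted p under 0.05). Within the batch that holds both stages the 443 bins differed by a mean of −0.16 and the 96 by 0.25. They were chosen with the arrays of that batch included, so these differences cannot weigh against the batch. A change in culture, such as a larger share of replicating cells, is a biological candidate that was not tested.

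The gain around Malt1 was larger in the line than at day 0 in 9 of 9 matched tumours. Suppose cells without the change diluted the day 0 DNA and were the whole cause. Day 0 would then show the same share of the line's excess at Malt1 as over the line's other segments of 5 Mb or longer. The share at Malt1 was lower by more than 2 standard errors in 5 of 9 tumours (141645, 161336, 122378, 67506 and 178119). In 141645 it was 0.0302 ± 0.00468 against 0.239 ± 0.0805 SE. Shares of single segments spread widely, however, from −0.466 to 1.71 in 141645 and from −0.293 to 1.66 in 122378. The day 0 array of 122378 also depended on the processing. The test therefore speaks against dilution as the whole cause in those 5 without excluding it. In the other 4 the share was within 2 standard errors and dilution stays open. The scan batch does not account for it, since the 4 tumours with both stages in 1 batch, each on 1 slide, rose by a mean of 2.35. Within the tumours, outgrowth of a subclone with many copies, or further gain during culture, may underlie the difference, and these data cannot separate the 2. Both are hypotheses that were not tested.

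Some lines part from their day 0 sample over the genome, with r as low as 0.478 in 141645, and 122378 at day 0 correlated better with another line (0.698) than with its own (0.624), though after GC correction 9 of 9 day 0 samples correlated best with their own line (122378 at 0.696). A mislabelled line would carry the immunoglobulin profile of another tumour, but 9 of 9 lines correlated best with the day 0 sample of their own number (exact one-sided permutation p = 2.76e-06; mean r 0.906 ± 0.038, n = 9). This argues against swaps among the 9 matched lines and says nothing of the 4 lines with no partner. Changes acquired in culture stay open and were not tested.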

How the results depend on the processing

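The settings by scan batch, those without the 2 noisiest arrays and those that join GC correction with a block or batch term were chosen only after the result was seen; the other alternatives were planned. Of 405 planned values of the results per comparison 307 kept their place, 3 were weaker and 95 moved, and of 37 added values 18, 2 and 17. Of 550 planned values of named genes and bins 507 kept their direction and side of the threshold, 40 were weaker and 3 reversed, and of 170 added values 134 kept theirs, 27 were weaker and 9 stronger. Weaker means here that a call was lost and stronger that one was won, whatever the size of the value. These tallies overstate stability. The 70 values from the deposited table were the same by construction. The named genes of day 0, none of them called, could change only by a new call or a change of sign. Where values moved the cause was not tested. Restricting the arrays leaves fewer of them, but this alone does not account for the later protocol. Its 6 lines kept the call of 13 named genes, while the 6 lines labelled as lacking Atm kept that of 30. Sign-flip tests on 6 lines cannot go below p = 0.0312, so that at least 12 of 19 autosomes or 4 of 6 loci would have to reach it; on 7 lines the limit is 0.0156, and 6 autosomes or 2 loci. Their adjusted counts of 0 below therefore say little about stability, while the unadjusted counts beside them could pass the threshold. The signal over background, 2.25 to 6.67 in the tumour channel, limits small shifts most on the dimmest arrays.

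With normexp the lines had 0 autosomes lost, 4443 genes gained, 794 lost and 0 receptor loci lost (exact test, 0 also at an unadjusted p under 0.05), day 0 had 2 recurrent gains, and 378 bins were higher. Its offset pulls the ratios of dim probes together, so the count of loci says little of deletions there. Centred on the mode 1 autosome was lost in the lines. With only probes well above background on all arrays 1 autosome and 0 loci were lost in the lines (1 and 0 unadjusted), but a deleted probe is dim, and that filter left 16 of 132 probes at Igh and 39 of 117 at Igk, so it says little of these loci. After GC correction the lines had 19.2% of the genome altered, 7 recurrent gains, 9 recurrent losses, 3649 genes gained and 1 locus lost, day 0 had 1 autosome gained and 1 locus lost, and 55 bins were higher. With no size limit 6 autosomes were gained and 6 lost in the lines and 1 and 1 at day 0, and limma called 11460 genes gained and 4927 lost in the lines and 3419 and 1369 at day 0. By the lowest 3 neighbouring probes 6 loci were lost in the lines and 4 at day 0, a measure that takes the lowest of many values.

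With the penalty doubled the lines had 18 recurrent losses. With a call limit of 0.3 they had 18 recurrent losses and 18.9% altered, and the stage difference was 9.74 points (p = 0.0710). With a call limit of 0.15 day 0 had 10 recurrent gains and 4 losses, and with stretches of 3 Mb or longer 3 and 1. The lines labelled as lacking Atm (n = 6) had 0 autosomes gained, 0 lost, 0 loci lost (1, 1 and 1 at an unadjusted p under 0.05), 9 recurrent gains and 10 losses. Those of the later protocol (n = 6) had 0, 0 and 0 (1, 0 and 1 unadjusted), 8 and 2, with 686 genes gained and 483 lost. Those of the earlier protocol (n = 7) had 0, 1 and 1 (0 autosomes gained unadjusted), 9 and 12.

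With the replicate block the stage difference in percent altered was 14.5 points (exact p = 0.121), and 5 bins were higher and 12 lower. In the 18 matched arrays unpaired it was 14.5 points (p = 0.0687), with 0 bins higher (limma, 96 at an unadjusted p under 0.05) and 6 lower. The protocol as a covariate gave 17 higher and 239 lower, the later protocol alone 5 and 9, and bins of 5 Mb 9 and 116, where fewer bins were tested. The scan batch as a covariate gave 0 and 0 (61 and 172 at an unadjusted p under 0.05), and with GC correction again 0 and 0 (63 and 270 at an unadjusted p under 0.05). Scan batch 3 alone gave 4 and 0, and a difference of 17.6 points (p = 0.271). GC correction with the block gave 9, 104 and 7.87 points (p = 0.0586). Without the 2 noisiest arrays 393 bins were higher and 723 lower, the lines had 19 recurrent losses and 1 locus lost, and day 0 had 1 autosome gained and 9 recurrent gains. Scan batch 2 alone gave day 0 3 recurrent gains, 1268 genes gained and 444 lost.

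Leaving out 1 array gave 1 to 3 autosomes gained and 1 to 2 lost in the lines, 0 to 1 gained and 0 to 0 lost at day 0, 1 to 3 loci lost in the lines and 0 to 1 at day 0. Genes ranged from 6730 to 8039 gained and 2429 to 2779 lost in the lines and stayed at 0 and 0 at day 0 (limma). Percent altered ranged from 31.3 to 35.8% and from 7.50 to 14.7%, its difference from 17.9 to 26.6 points, bins higher from 28 to 405, bins lower from 257 to 752, and the correlation of matched tumours from 0.646 to 0.699. Among named genes Relb in the lines went from 0.43 to −0.037 after GC correction, Mef2b at day 0 from 0.17 to −0.022, and Foxo1 at day 0 from −0.015 to 0.081 with the window of 100 kb. Calls were lost for 17 of 30 named genes of the lines with the later protocol alone, and for 10 of 70 named genes and bins after GC correction, besides the reversed Relb. In the 18 matched arrays unpaired 7 of 10 bins lost theirs, and with the scan batch as a covariate 10 of 10. A lost call was not always a smaller value. With the later protocol Akt1 lay at 0.94, above its mean in all lines, while Hace1 (−0.32) was smaller in size. With the scan batch as a covariate the chromosome 18 bins differed by more, as at Malt1 (1.91 against 1.51), and those near Tjp1 and Olfr385 by less.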

Other observations

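All tests in this part were chosen only after the result was seen. The far end of chromosome 18 fell together with the gain at Malt1. Over 85150701 to 90762649, with Socs6, a suppressor of cytokine signalling, and Rttn, a gene needed for centrioles, the mean was −1.07 ± 0.43 in the lines (n = 13) and −0.26 ± 0.23 at day 0 (n = 10), below 0 in 13 of 13 and in 10 of 10. The line was lower in 9 of 9 matched tumours, by a mean of −0.77 ± 0.41 (exact two-sided sign-flip p = 0.00391, the smallest that 9 pairs allow), and in 4 of 4 within scan batch 3 (mean −1.01). The lowest day 0 value was that of 180764 (−0.82), which also had the highest Malt1 value at day 0.

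The gain on chromosome 3 with Bcl10 went the other way in several tumours. Over 143172609 to 149435884 the mean was 0.53 ± 0.42 at day 0 (n = 10) and 0.26 ± 0.36 in the lines (n = 13). The line was lower in 6 of 9 matched tumours, by a mean of −0.19 ± 0.39 (exact p = 0.180), so no difference was shown. In 161336 the value was 1.29 at day 0 and 0.24 in the line, in 141645 0.48 and −0.03, while in 67506 it was 0.91 and 0.89 and in 122378 0.41 and 0.68.

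The day 0 sample 123203 and the line 12303 have numbers that differ by 1 digit and no partner of their own. A candidate explanation is 1 tumour under 2 numbers. Over the 249 immunoglobulin probes their r was 0.945, just above the range of the 9 matched tumours (0.850 to 0.942), while 123203 reached at most 0.260 with another line and 12303 at most 0.162 with another day 0 sample. The highest r between unmatched samples was 0.828. Over the 1 Mb bins their r was 0.594, against 0.484 with the next line. They were kept unpaired in every comparison.

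Tcrg, a T cell receptor locus of 7 probes, ranged from −0.67 to 1.21 over the 23 arrays, and the sign followed the scan batch. All 10 arrays of scan batch 3 lay below 0, and all 13 of scan batches 1 and 2 above. In 8 of 9 matched tumours both stages lay on the same side of 0, and the exception, 67506 (0.38 at day 0 and −0.52 in the line), is the only one with a single stage in scan batch 3. In the other 8 both stages lay inside scan batch 3 or both outside it, so they cannot separate tumour from batch. In 67506 the sign went with the batch. It also did in 123203 at day 0 (0.13, scan batch 2) and the line 12303 (−0.67, scan batch 3), should these be 1 tumour. The cause was not tested.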
